A study of Mus musculus with 40 samples.

How the data were processed

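Messenger RNA was measured on 40 one-colour arrays of MLE-12 cells, 4 in each of 10 groups, and the groups were taken from the sample labels. The labels name miR-467c where the series text names miR-476c, and the labels were followed, so which of these was transfected rests on them. Per the labels, RNA was isolated with a miRNeasy kit 24 h after transfection, from cells at passage 4, and labelled with Cy3. The labels give an input of 100 ng for labelling, while the series text gives another amount, and which of them applied stays unknown. The labels call the arrays of a group biological replicates, but they do not state whether each came from its own transfection or culture, so p-values here measure the spread between these arrays. The arrays sat on 5 slides of 8 arrays each.

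The deposited scanner files hold, per the file headers, intensity values that Agilent Feature Extraction 10.7.3.1 computed for array design 028005, with the processed signal being background-subtracted and detrended within 1 array and not normalised between arrays. The submitters' processing notes name version 10.7.1.1 and list the package affy without saying what it did. Each array carried 59305 gene spots and 3671 control spots, and the gene spots covered 55681 different probes. The deposited series matrix holds log2 values for 52095 probes, per its values, close to log2 of the processed signal, and its column medians of 4.48 to 5.21 show that the authors brought the columns near each other. Which method set that scale and centring is not stated, while the direction of a difference is that of the signal. Of its 40 columns, 35 correlated best with the scanner file of the same label. The columns of miR-337 precursor replicates 2 and 3 and of miR-467c precursor replicates 1, 2 and 3 correlated best with another array of the same group, so replicate numbers here are those of the scanner files, and group comparisons are unaffected.

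Probe names were matched through the transcript identifiers in the files to the symbols of the reference annotation. This gave 20018 symbols for 26413 probes and left 29268 probes without a symbol. The headers name mouse build mm9 and the annotation is on a later build, so names were taken from it and no coordinates are given. Spots of a probe were averaged, signals below 1 were set to 1, and log2 of the processed signal minus the array's own 75th percentile is the level used throughout. A probe was kept when the scanner called it well above background on at least 4 arrays, which left 32790 probes. Each gene was represented by its probe with the highest mean, giving 24009 features, of which 14129 had a symbol. Features without a symbol enter the counts and are not named.

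Group means were fitted across 40 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A feature passed at an adjusted p below 0.05, and SE is the moderated standard error. Each precursor group was compared with the precursor control and each inhibitor group with the inhibitor control, and 3 further comparisons set the controls, the miR-30a and miR-30d inhibitors, and the miR-466a and miR-466d precursors against each other. With 4 arrays on each side, an exact permutation test of 1 gene cannot give a two-sided p below 0.0286, and at a p below 0.05 chance alone would give about 1200 features in each comparison. The number of arrays limits the precision.

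The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names, for each treatment, up to 10 of the largest rises and 10 of the largest falls among passing genes with a proper name whose 4 arrays all lie on the same side of every control array. It takes 3 of each for the other comparisons and the 3 lowest p-values where fewer than 10 genes pass. It also names up to 4 passing members of each called list and of the lists of reported microRNA targets. Its part on genes with a site for the transfected microRNA was not applied, because sites in 3' untranslated regions were not analysed here. The 28 lists held 658 genes, of which 589 were tested. Lists were tested with camera, which asks whether a list's genes shifted against all other genes, at a preset correlation of 0.01 between genes, over 23671 features with a value on every array, again with an estimated correlation, and with fry. Genes of a list were also adjusted over the list alone. Values are also given within slides that hold both groups, by difference of group means on each slide, and with slide as a block in the fit.

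Replicate 2 of the miR-337 precursor differed strongly from all other arrays, and a fit without it was chosen after the data were seen. Both fits are given as the fit of 40 arrays and the fit of 39 arrays, and the naming rule was applied to each. Outside the miR-337 group the log2 changes are identical in both fits, and what differs is the spread between arrays that limma shares across groups, with a median SE of 0.221 in the fit of 40 arrays and 0.164 in that of 39. Alternatives were normexp background correction on the median spot signal, since the mean signal is not among the columns, with an offset of 50. Others were quantile normalisation, a 75th percentile over probes above background on all arrays, and the series matrix. Probes and samples were varied by no filter or a stricter filter on dim probes, the mean of a gene's probes, slide or replicate number as a block, a fit of only the 8 arrays compared, and each array left out in turn. Array weights, the fit of 39 arrays with its own alternatives, and a fit without sets of probes that vary together were added after the data were seen.

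Where a gene was not well above background on any array of one group, miR-337 precursor replicate 2 left aside, its change is given only as a bound, computed from the lowest signal that the scanner called above background. The pipeline was tested on simulated data made from these arrays, with 200 of 23671 features changed in each of 5 draws. Deviations of the miR-337 precursor arrays were taken from a group mean that included replicate 2, also where that array was left out. The simulated spread with 39 arrays is therefore not exactly that of the fit. With 40 arrays the deviations of all arrays were shuffled over all groups, so that those of replicate 2 could fall into any group. In the real fit that array is always in the miR-337 precursor group. Recovery and calls elsewhere simulated with 40 arrays therefore do not describe the real fit of 40 arrays. For the miR-23b inhibitor comparison the fit of 39 arrays recovered 69.6% of changes of 1.0 log2 and 17.4% of changes of 0.5, with 1 call elsewhere per draw, and the fit of 40 arrays recovered 50.8% and 9.6%, with 63.4 calls elsewhere. For the miR-337 precursor these were 60.8% and 11.8% with 1 call elsewhere in the fit of 39 arrays, and 52% and 19% with 9.2 in that of 40. For the miR-466a precursor they were 69% and 13.2% with 1.8 calls elsewhere in the fit of 39 arrays, and 49.2% and 4.6% with 1 in that of 40. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.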

Results

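Gene expression was measured in MLE-12 cells, a mouse line of distal lung epithelium transformed with the SV40 large T antigen, 24 h after transfection with a microRNA precursor, a microRNA inhibitor or a control RNA. A precursor supplies a microRNA to the cell, and an inhibitor binds a microRNA and blocks it. Per the series text, the inhibitors were aimed at microRNAs that are abundant in these cells, and the precursors supplied microRNAs that are almost undetectable in them. The 10 groups held 4 arrays each: inhibitors of miR-23b, miR-30a, miR-30d and miR-125a with an inhibitor control, and precursors of miR-337, miR-466a, miR-466d and miR-467c with a precursor control. The amount of the mature microRNAs was not measured by these probes, so the effect of each transfection on its own microRNA is not given here. The surfactant genes Sftpc and Sftpb, markers of alveolar type 2 cells, lay at log2 levels of 3.18 ± 0.42 and 3.32 ± 0.31 (SD, 39 arrays) above the array's 75th percentile. The lipid transporter gene Abca3 lay at 4.46, the lung transcription factor gene Nkx2-1 at 2.28 and the keratin gene Krt8 at 5.09. The leukocyte gene Ptprc and the surfactant gene Sftpa1 were above background on 1 array each. On 39 arrays 44.3 to 60.8% of probes were well above background, and on miR-337 precursor replicate 2 this was 91.8%, with a median correlation to the other arrays of 0.774 where the other arrays reached 0.9745 to 0.9917.

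**Figure D1:**
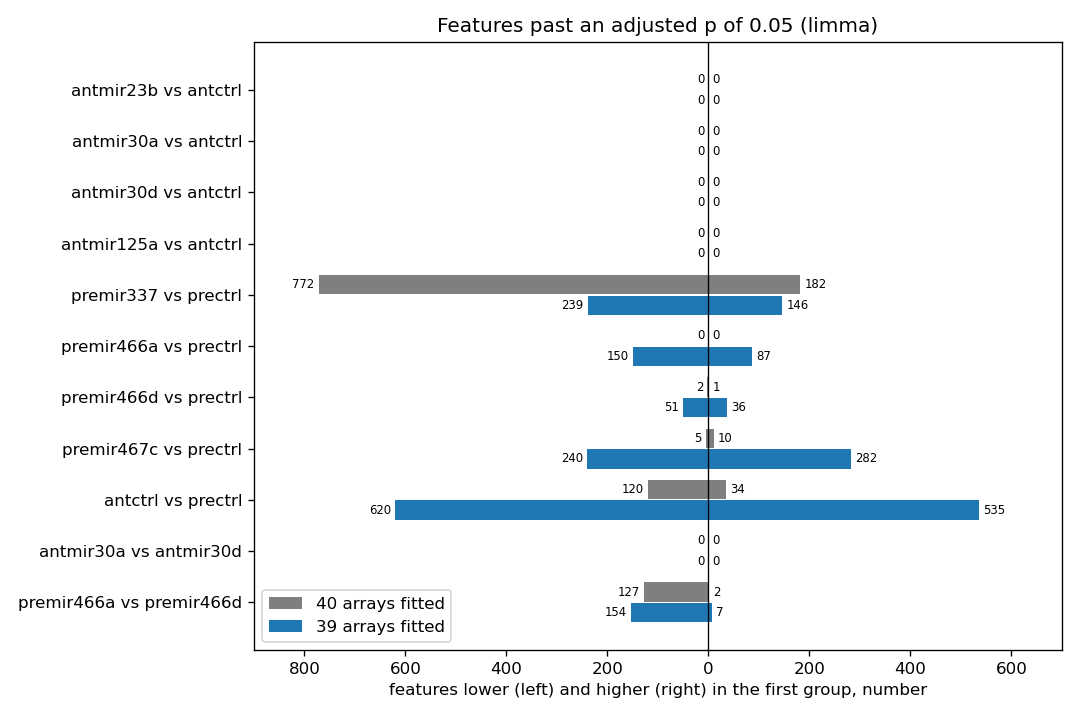
Number of features past an adjusted p of 0.05 in each of the 11 comparisons, with features lower in the first group drawn to the left and features higher drawn to the right, for the fit of 40 arrays (grey) and the fit of 39 arrays (blue). The 4 inhibitor comparisons stand at 0 in both fits, and the miR-337 precursor goes from 772 lower and 182 higher features to 239 and 146.

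Ahr, the transcription factor that senses dioxin-like compounds, and Plau, the urokinase plasminogen activator, were lower with the miR-337 precursor than in the precursor control. Ahr changed by -1.50 ± 0.20 (log2, SE; limma adjusted p = 8.7e-05) in the fit of 40 arrays and by -1.17 ± 0.15 (adjusted p = 1.9e-05) in that of 39. Its mean went from 1.33 ± 0.08 (SD, n = 4) in the control to 0.17 ± 0.29 (n = 3). The control was the highest group for Ahr, since the means of the 8 other groups lay at 0.61 to 0.91. Plau changed by -1.16 ± 0.16 (adjusted p = 8.7e-05) and, with 39 arrays, by -1.09 ± 0.16 (adjusted p = 5.3e-05). The adhesion gene Cdh1, which encodes E-cadherin, rose by 0.72 ± 0.13 (adjusted p = 0.0019) and 0.69 ± 0.12 (adjusted p = 0.0011) in the same fits. Tff1, a secreted peptide of mucous surfaces, rose by 1.102 ± 0.25 (adjusted p = 0.012) and 1.49 ± 0.21 (adjusted p = 4.6e-05). Atp6v0a4, a subunit of the proton pump, rose by 1.20 ± 0.24 (adjusted p = 0.0047) and 1.52 ± 0.21 (adjusted p = 2.6e-05). These 5 genes passed in every fit of 39 arrays that left out 1 further array. With slide as a block they changed by -1.18, -1.09, 0.68, 1.503 and 1.51.

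Further genes fell in both fits. The phosphatidate phosphatase gene Lpin1 changed by -0.85 and -0.73 (40 and 39 arrays), and Ppargc1a, a coactivator of mitochondrial biogenesis, by -0.94 and -1.16. The caveolar scaffold gene Cav1 changed by -0.99 and -0.74, and the metalloprotease gene Adam19 by -0.94 and -0.71. The peptide hormone gene Apln changed by -1.30 and -0.91, and Reep3, which shapes the endoplasmic reticulum, by -1.22 and -0.80. Cracd (-1.35 and -1.03), the phosphatase genes Ppm1h (-1.31 and -0.94) and Ptprr (-1.30 and -1.02), Cyb561a3 (-1.21 and -0.92), Megf10 (at least 2.10-fold lower with 39 arrays) and Papln (-1.39 and -1.43) fell as well. So did the oxygen sensor gene Egln3 (-0.72 and -0.47). Rises in both fits were the growth factor gene Csf2 (0.91 and 1.17), Fam25c (1.57 and 1.18), Serpinb1c (1.93 and 1.47), Sycn (1.54 and 0.79), Apol7a (1.32 and 0.81) and Ddn (1.28 and 1.44). Of 41 genes that the rule named and that passed with 39 arrays, 18 passed whichever further array was left out and 38 passed with slide as a block.

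Interferon-stimulated genes, which encode antiviral proteins, stood higher with the miR-337 precursor, and the size of this shift differed widely between its arrays. Ifit3 rose by 1.39 ± 0.40 (limma adjusted p = 0.041) and Ifit3b by 1.64 (adjusted p = 0.043) in the fit of 40 arrays, and by 1.82 ± 0.40 and 2.00 with 39. With 39 arrays Rsad2 rose by 1.26 ± 0.23 (adjusted p = 0.0014), the nucleic acid sensor gene Zbp1 by 1.33, Tgtp2 by 1.32 and Cmpk2 by 1.21, and these 4 did not pass with 40. The list shifted by a median of 0.77 with 39 arrays (camera adjusted p = 2.0e-19; adjusted p = 0.446 with an estimated correlation). With 39 arrays 9 of its 40 genes rose, none fell and 31 did not pass, or 23 when adjusted over the list alone. With 40 arrays the shift was 0.38 (adjusted p = 1.2e-06; adjusted p = 0.592 with an estimated correlation), with 1 riser, or 4 adjusted over the list alone. Median levels of the interferon-stimulated genes were 1.45, -0.08 and 0.44 on replicates 1, 3 and 4 and -1.07 on replicate 2, against -0.41 to 0.10 in the control. Without replicate 1 the shift with 39 arrays was 0.38. Ifit3, Ifit3b, Tgtp2, Zbp1 and Cmpk2 then no longer passed, at adjusted p of 0.25, 0.39, 0.31, 0.27 and 0.26, while Rsad2 passed at 1.07 (adjusted p = 0.040). Without replicate 1 the shift in the fit of 40 arrays was -0.08. Differences on single slides ran from -0.07 to 1.34, upwards on 2 of 3 slides, and the slide block gave 0.67.

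**Figure D2:**
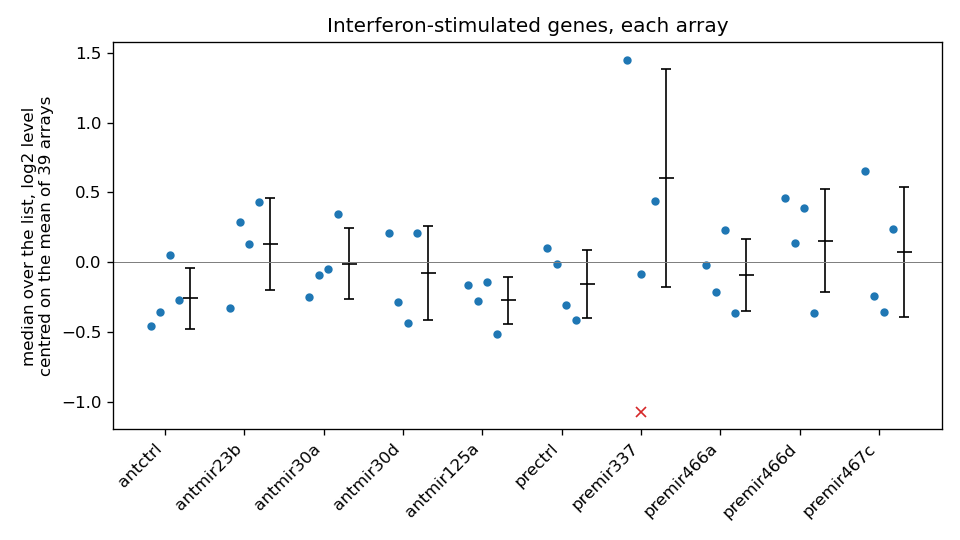
Median level of the interferon-stimulated genes on each array (log2, centred on the mean of 39 arrays) in the 10 groups, with blue points for arrays, black bars for the mean and SD, and a red cross for miR-337 precursor replicate 2, which the bars leave out. The miR-337 precursor arrays spread from -1.07 to 1.45.

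Epithelial junction and keratin genes also stood higher with the miR-337 precursor, by a median of 0.22 with 39 arrays (camera adjusted p = 0.0104; adjusted p = 0.176 with an estimated correlation). With 40 arrays the shift was 0.15 (adjusted p = 0.0258; adjusted p = 0.592 with an estimated correlation). Cdh1 and Krt8 (0.56 ± 0.11, limma adjusted p = 0.0032) rose with 39 arrays, 22 of the 24 genes did not pass, and 4 rose when adjusted over the list alone. The shift was 0.06 to 0.25 on all 3 shared slides and 0.22 with the slide block. In fits of 40 arrays it was -0.02 under quantile normalisation and -0.14 over probes above background on all arrays. Reported targets of miR-23 stood lower, by -0.18 (adjusted p = 0.0231; adjusted p = 0.703 with an estimated correlation), with Plau and Ppargc1a as the 2 of 28 that fell. With 40 arrays the shift was -0.36, slides gave -0.22 to -0.05, the slide block gave -0.18, and without replicate 1 the adjusted p with 39 arrays was 0.14. The inflammatory list stood higher by 0.08 (adjusted p = 0.0104; adjusted p = 0.476 with an estimated correlation). Csf2 and the chemokine gene Ccl5 (1.00 ± 0.19, limma adjusted p = 0.0023) were the 2 of 20 that rose, or 4 adjusted over the list alone. Its shift ran from -0.01 to 0.26 on slides, was 0.11 with the slide block and 0.04 with 40 arrays, where it was not called (adjusted p = 0.0502), and its adjusted p was 0.053 without replicate 3.

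The number of features that changed with the miR-337 precursor rested on replicate 2. The fit of 40 arrays gave 182 higher and 772 lower features, of which 93 and 604 had a symbol and 174 and 723 changed at least 1.5-fold. With 39 arrays 146 were higher and 239 lower, with 102 and 193 named and 98 and 121 at least 1.5-fold. The median change of all features went from -0.21 to -0.01. Normexp correction gave 83 and 690 with a median of -0.18, quantile normalisation 139 and 731 with -0.17, the percentile over probes above background 628 and 504 with 0.13, and the series matrix 442 and 557. The fit of 40 arrays called 3408, 6279 and 6144 features without miR-337 precursor replicates 1, 3 and 4, and 216, 205, 301 and 448 without control replicates 1 to 4. The fit of 39 arrays called 121, 232 and 240 without replicates 1, 3 and 4, and 225 and 194 without control replicates 1 and 2. Of 28 lists, 21 were called with 40 arrays and 4 with 39, none of them with an estimated correlation. The lists called only with 40 arrays comprised the S phase, G2/M, p53, unfolded protein response, glycolysis, oxidative phosphorylation, ribosomal, heat shock, TGF-beta, extracellular matrix, apoptosis, RNA silencing, lipid synthesis and alveolar type 1 lists. They also comprised the miR-125 target list, a list of ubiquitin ligase and calcineurin genes with miR-30 sites, and, upwards, the club cell and leukocyte lists. Genes from them that passed with 40 arrays alone were Atf4, Bcl2l1, Bmf, Canx, Cbfb, Ccne1, Chac1, Ect2, Klhl20, Ndrg1, Pmaip1, Tgif1, Tnrc6c and Zmat3, all lower by -1.01 to -0.64. Among the largest rises, Entpd8, Ucma, and Smim6, Magix and Cst9, which lay near background, passed with 40 arrays alone. Without replicate 2 Entpd8 was at least 1.75-fold higher. Tigit (1.68), Echdc1 (at least 1.55-fold lower) and Srgap1 (-1.27) passed with 39 alone, as did Plch2 and Lhx9, whose falls were near background and are not given as folds.

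**Figure D3:**
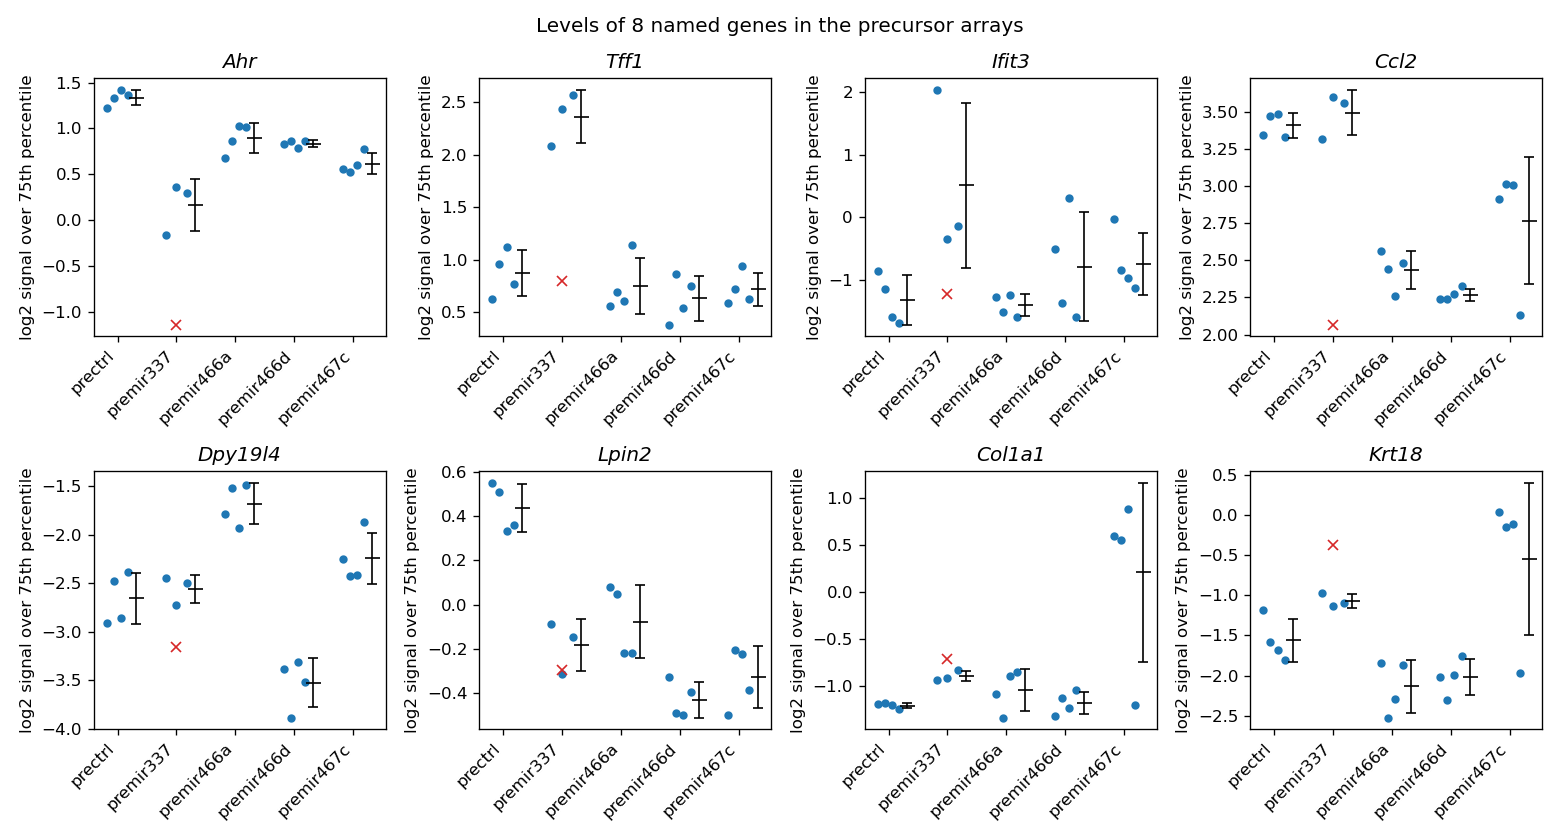
Levels of 8 named genes (log2 signal over the array's 75th percentile) on each array of the precursor control and the 4 precursor groups, with blue points for arrays, black bars for the mean and SD, and a red cross for miR-337 precursor replicate 2, which the bars leave out. Dpy19l4 lies at -1.68 on average with the miR-466a precursor and at -3.52 with the miR-466d precursor, and 1 of the 4 miR-467c precursor arrays lies apart for Col1a1 and Krt18.

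With the miR-466a precursor no feature passed in the fit of 40 arrays, where the smallest adjusted p was 0.0765 and 843 features had an unadjusted p below 0.05 (limma). With 39 arrays 87 features were higher and 150 lower, 46 and 129 of them at least 1.5-fold, with 2108 at an unadjusted p below 0.05. There Id2, an inhibitor of helix-loop-helix transcription factors, rose by 1.15 ± 0.20 (log2, SE; limma adjusted p = 0.0021), from -1.40 ± 0.20 to -0.25 ± 0.21 (SD, n = 4 each). Slurp1, a secreted regulator of epithelial cells, rose by 1.16 ± 0.19 (adjusted p = 0.0012), Dpy19l4, a relative of the C-mannosyltransferases, by 0.98 ± 0.15 (adjusted p = 0.00071) and the histone gene H2bc8 by 1.48 ± 0.38 (adjusted p = 0.041). Ccl2, the chemokine that attracts monocytes, fell from 3.41 ± 0.08 to 2.44 ± 0.13, a change of -0.97 ± 0.15 (adjusted p = 0.00047). The leukocyte receptor gene Cd300a changed by -1.78 ± 0.32 (adjusted p = 0.0028) and the interleukin receptor gene Il4ra was at least 2.58-fold lower (adjusted p = 0.0051), although the other probe of Il4ra did not share its sign. Ccl2 and Slurp1 also differed between the inhibitor control and the precursor control, by -0.90 and 1.11, and Ccl2 lay at 2.51 in the inhibitor control. Id2, Slurp1, Dpy19l4, Ccl2, Cd300a and Il4ra passed in all 8 fits of 39 arrays that left out 1 further array.

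Most features lower with the miR-466a precursor belonged to a set of 130 probes that varied together across all groups. It held 104 of the 150 lower features. Golt1a (-1.57), Nhlh1 (-1.47), Arhgap26 (-1.32), Eya1 (-1.28), Madd (-1.23), Ldlrad3 (-1.22) and Zcchc9 (-1.21) are in it. The largest rises Krt222 (1.23), Idua (1.19), Slc17a5 (1.17), Fgf23 (1.16), Tacr2 (1.11), Oprm1 (1.08) and Pdcd4 (1.07) are in another set, which held 16 features that passed. That set lay at 2.75 ± 0.44 (SD, n = 4) with the miR-466a precursor. In the control it lay at 1.71 ± 0.70 (n = 4), with replicate 2 at 0.75. Other probes for the genes of the set of 130, 54 in all, changed by a median of -0.04. For the set that rose this median was not computed. Over 39 arrays 8 other probes of its genes had a median correlation of -0.17 with its mean. Other probes of Idua and Slc17a5 changed by -0.20 each, so rises of the transcripts are not shown. The set of 130 is set 2 and the set that rose is set 5, and without co-varying probe sets 2, 3 and 5 73 features passed. There H2bc8, which is in none of these sets, kept its change of 1.48 and lost its call (limma adjusted p = 0.0804). Without miR-466a precursor replicate 1, 96 features passed, without replicate 2, 140, and without control replicates 1 and 2, 123 and 115. Over 40 arrays the count was 28 with normexp correction, 120 with quantile normalisation, 194 with the percentile over probes above background, 179 with the series matrix and 2 with the mean of a gene's probes.

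**Figure D4:**
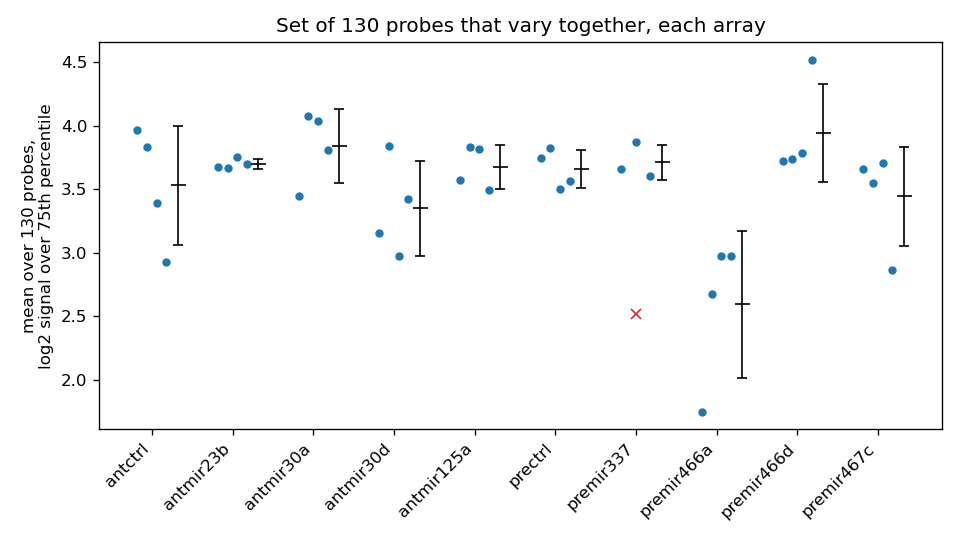
Mean level of the set of 130 probes (log2 signal over the array's 75th percentile) on each array in the 10 groups, with blue points for arrays, black bars for the mean and SD, and a red cross for miR-337 precursor replicate 2, which the bars leave out. The miR-466a precursor arrays lie at 1.75 to 2.98 and the precursor control arrays at 3.50 to 3.83.

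Gene lists moved little with the miR-466a precursor. Mitosis genes of the G2/M list stood higher by a median of 0.13 (camera adjusted p = 2.0e-05 with 39 arrays and 0.00064 with 40; adjusted p = 0.130 with an estimated correlation). They stood higher by 0.01 to 0.20 on the 3 shared slides and by 0.14 with the slide block, and none of the 35 genes passed. Cholesterol synthesis genes stood higher by 0.15 (adjusted p = 0.0021; adjusted p = 0.285 with an estimated correlation), by 0.03 to 0.16 on slides and 0.15 with the block. Targets of p53 stood higher by 0.10 (adjusted p = 0.0141; adjusted p = 0.290 with an estimated correlation), by 0.01 to 0.13 on slides and 0.11 with the block. None of the 25 and 20 genes of these lists passed. The inflammatory list stood lower by -0.09 (adjusted p = 0.0313; adjusted p = 0.290 with an estimated correlation), with Ccl2 as its 1 fall of 20 genes, or 2 adjusted over the list alone. It stood at -0.20 to -0.04 on slides, and its adjusted p with the slide block was 0.074. TGF-beta response genes stood higher by 0.09 (adjusted p = 0.0070; adjusted p = 0.285 with an estimated correlation), with Id2 as the 1 of 23 that rose, and by 0.02 without control replicate 4 (adjusted p = 0.061). It ran from -0.06 to 0.25 on slides, upwards on 2 of 3. Glycolysis genes (0.09, adjusted p = 0.0379; adjusted p = 0.285 with an estimated correlation) and reported miR-30 targets (0.06, adjusted p = 0.0348; adjusted p = 0.290 with an estimated correlation) were called with 39 arrays alone. The glycolysis shift was 0.09 to 0.16 on slides and -0.02 with normexp correction, and that of miR-30 targets was -0.09 to 0.17 on slides.

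Ccl2 and Lpin2 were lower and Cd248 was higher with the miR-466d precursor than in the precursor control, and these were the 3 features that passed in the fit of 40 arrays. Lpin2, a phosphatidate phosphatase of lipid synthesis, changed by -0.86 ± 0.13 (log2, SE; limma adjusted p = 0.0010), from 0.44 ± 0.11 to -0.43 ± 0.08 (SD, n = 4 each). Ccl2 changed by -1.14 ± 0.21 (adjusted p = 0.034), from 3.41 ± 0.08 to 2.27 ± 0.04, and Cd248, a surface glycoprotein of stromal cells, by 1.02 ± 0.18 (adjusted p = 0.013). With 39 arrays these 3 reached adjusted p of 4.1e-05, 4.1e-05 and 0.00015. When 1 array was left out of the fit of 40, Lpin2 passed in 8 of 8 runs, Cd248 in 4 and Ccl2 in 0, with Ccl2 at an adjusted p of 0.21 without control replicate 2. With 39 arrays all 3 passed in every run. The same genes also differed between the inhibitor control and the precursor control, by -0.90 for Ccl2, -0.65 for Lpin2 and 0.85 for Cd248 (39 arrays). So did Crb2 (-0.83), Slurp1 (1.11), H1f2 (0.37), Plac9a (0.59) and Rbm18 (0.48), and Smim6 and Cst9 were higher in the inhibitor control too. H2bc4 (0.20), Slpi (-0.61) and Tmem170 (-0.15) did not pass between the controls.

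With the miR-466d precursor 36 features were higher and 51 lower in the fit of 39 arrays, with 2506 at an unadjusted p below 0.05 (limma) where the fit of 40 gave 862. Among the falls were Dpy19l4 (-0.87 ± 0.15, adjusted p = 0.0031), the Argonaute gene Ago3 (-0.91 ± 0.20, adjusted p = 0.033), the protease inhibitor gene Slpi (-0.91), the apical polarity gene Crb2 (-0.88), Zfp568 (-0.82), Acin1, Pgm5 and Tmem170 (-0.77 each). Among the rises were Slurp1 (1.17 ± 0.19, adjusted p = 0.0011), the histone genes H1f2 (0.72 ± 0.10, adjusted p = 0.00015) and H2bc4 (0.62). Further rises were the ferritin gene Fth1 (0.62 ± 0.15, adjusted p = 0.042), Plac9a (0.73), Rbm18 (0.73) and Tmem9b (0.63), with Cst9 at least 1.37-fold and Smim6 at least 1.09-fold higher. Of 20 named genes that passed with 39 arrays, 9 passed whichever further array was left out, and Ago3 had an adjusted p of 0.15 without control replicate 2. Leaving out a further array gave 31 to 50 features, each below the 87 of the full set. It gave 31 without control replicate 1 or 2, 47 and 34 without control replicates 3 and 4, and 43, 37, 48 and 50 without miR-466d precursor replicates 1 to 4. Quantile normalisation gave 26 features, the percentile over probes above background 99 and the series matrix 79 in the fit of 40.

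Genes of the RNA silencing machinery, which load and carry out microRNA repression, stood lower with the miR-466d precursor by a median of -0.20, with a camera adjusted p of 1.3e-05 with 39 arrays. This was the only list call in the study's comparisons that held when the correlation was estimated (adjusted p = 0.0121 with an estimated correlation with 39 arrays, and 0.669 with 40). The shift was -0.29 to -0.11 on all 3 shared slides and -0.20 with the slide block, and it passed in every run that left out an array. In this list 1 of the 22 genes, Ago3, fell, or 2 adjusted over the list alone. The list lay at 0.11 in the precursor control and at -0.07 with miR-466d (log2, centred on the mean of 39 arrays), so that a high control is part of the shift. Inflammatory genes stood lower by -0.16 (adjusted p = 2.4e-05; adjusted p = 0.114 with an estimated correlation), at -0.28 to -0.11 on slides, with 1 fall among 20 genes, Ccl2, or 5 adjusted over the list alone. Apoptosis regulators stood lower by -0.15 (adjusted p = 5.8e-05; adjusted p = 0.165 with an estimated correlation), where none of 27 genes passed and 1 fell adjusted over the list alone. Lower too were reported targets of miR-23 (-0.10, adjusted p = 0.0037; adjusted p = 0.306 with an estimated correlation; -0.20 to 0.0068 on slides) and of miR-125 (-0.08, adjusted p = 0.0037; adjusted p = 0.212 with an estimated correlation). The miR-23 target list lay at 0.09 in the precursor control and at -0.01 with miR-466d (log2, centred on the mean of 39 arrays). For this list the control stood high while the miR-466d precursor lay near that mean. Ribosomal protein genes stood higher by 0.23 (adjusted p = 3.6e-08; adjusted p = 0.420 with an estimated correlation) and at -0.02 under quantile normalisation, with none of 32 genes passing. Interferon-stimulated genes stood higher by 0.35 (adjusted p = 0.00016; adjusted p = 0.747 with an estimated correlation), at 0.15 to 0.80 on slides, with none of 40 passing. Oxidative phosphorylation genes stood higher by 0.11 (adjusted p = 0.0166; adjusted p = 0.747 with an estimated correlation) and by 0.05 without miR-466d precursor replicate 4 (adjusted p = 0.38), and were not called with 40 arrays (adjusted p = 0.219). The erythroid list, 3 genes, was called with 40 arrays alone (0.37, adjusted p = 0.0395; adjusted p = 0.308 with an estimated correlation).

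The collagen gene Col1a1 was higher and Cdh4, which encodes R-cadherin, and Lpin2 were lower with the miR-467c precursor than in the precursor control. Col1a1 rose by 1.41 ± 0.24 (log2, SE; limma adjusted p = 0.0078 with 40 arrays and 0.0017 with 39), from -1.20 ± 0.03 to 0.21 ± 0.95 (SD, n = 4 each). Palm3, a membrane-associated protein gene, rose by 1.21 ± 0.21 (adjusted p = 0.0078), the homeobox gene Tlx2 by 1.24 ± 0.26 (adjusted p = 0.039), Sh3bgr by 1.17, the kinase gene Map4k1 by 0.96 and Ddit4l, an inhibitor of mTOR signalling, by 0.93. Cdh4 changed by -1.33 ± 0.25 (adjusted p = 0.019), Crb2 by -1.04 ± 0.20 (adjusted p = 0.023), Popdc3 by -0.84 and Lpin2 by -0.76 ± 0.13 (adjusted p = 0.0078). Crb2 and Lpin2 also differed between the inhibitor control and the precursor control, by -0.83 and -0.65. These 10 named genes were among 10 higher and 5 lower features with 40 arrays. Each lost its call in at least 1 run that left out an array, and Crb2 and Ddit4l did not pass with the slide block (adjusted p = 0.089 and 0.074). With 39 arrays all 10 passed in every such run. Of 37 named genes that passed with 39 arrays, 12 passed whichever further array was left out and 29 passed with slide as a block.

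Replicate 4 of the miR-467c precursor lay apart from the other 3 arrays of its group for several of these genes. Col1a1 lay at -1.20 on it and at 0.56 to 0.88 on the others, so that the rise was 1.88 without it and 1.19 without replicate 3. Palm3 lay at -1.06 against 0.12 to 0.20, with a rise of 1.51 without it. Krt18, a keratin of simple epithelia, passed only with 39 arrays (1.01 ± 0.26, limma adjusted p = 0.029) and lay at -1.96 on replicate 4 against -0.15 to 0.04. Its rise was 1.48 without that array (adjusted p = 2.2e-06) and its adjusted p was 0.16 without replicate 3. The collagen gene Col1a2 rose by 1.11 with 39 arrays and by 1.48 without replicate 4. Without that array the features called went from 15 to 124 in the fit of 40 arrays and from 522 to 1151 in the fit of 39. Without replicates 1, 2 and 3 the latter gave 112, 115 and 105, with 260 and 188 without control replicates 1 and 2. In the fit of 40 arrays the count was 0, 1 and 1 without replicates 1, 2 and 3, and 0, 4, 6 and 6 without control replicates 1 to 4.

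With the miR-467c precursor 282 features were higher and 240 lower in the fit of 39 arrays, 120 and 133 of them at least 1.5-fold, and 3777 features at an unadjusted p below 0.05 (limma) where the fit of 40 gave 1474. Quantile normalisation gave 34 and 34, the percentile over probes above background 139 and 223, and the series matrix 141 and 123 in fits of 40 arrays. Rises with 39 arrays alone included H2bc8 (1.46), Gprasp2 (1.32), the RNA genes Rprl2 (1.14), Snora74a (1.06) and Malat1 (0.93), and Kcnj10, at least 1.57-fold higher. Falls included the collagenase gene Mmp13 (-1.18, adjusted p = 0.013), the fructose transporter gene Slc2a5 (-1.22) and Hivep3 (-1.42). Among genes near background, Mrrf was at least 1.68-fold, H2-T3 at least 1.53-fold, Fam205a2 at least 1.26-fold, Mecom at least 1.0999-fold, Thpo at least 1.02-fold and Dydc2 at least 1.01-fold lower.

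Target genes of p53 stood higher with the miR-467c precursor by a median of 0.32, by 0.41 on the 1 slide that holds both groups and by 0.34 with the slide block. The camera adjusted p was 1.9e-06 with 39 arrays and 4.5e-05 with 40 (adjusted p = 0.112 with an estimated correlation with 39), and the shift passed in all 8 runs that left out a further array. The mTOR inhibitor gene Ddit4 (0.63, limma adjusted p = 0.011), the p53 ligase gene Mdm2 (0.48, adjusted p = 0.030) and the apoptosis effector gene Perp (0.32, adjusted p = 0.0496) were the 3 of 20 that rose with 39 arrays, or 9 adjusted over the list alone. Cholesterol synthesis genes stood higher by 0.19 (adjusted p = 0.00061; adjusted p = 0.202 with an estimated correlation), by 0.21 within the slide and 0.15 with the block. In this list 1 of 25 genes rose, or 3 adjusted over the list alone. The mesenchymal list stood higher by 0.10 (adjusted p = 0.0283; adjusted p = 0.112 with an estimated correlation), with Col1a1 and Col1a2 the 2 of 19 that rose, or 4 adjusted over the list alone. Its adjusted p with the slide block was 0.079. The junction and keratin list stood higher by 0.13 (adjusted p = 0.0341; adjusted p = 0.202 with an estimated correlation), with Krt18 the 1 of 24 that rose, or 2 adjusted over the list alone, and 0.064 was its adjusted p with the block.

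Further lists were called with the miR-467c precursor and 39 arrays. Ribosomal protein genes stood higher by 0.20 (camera adjusted p = 2.0e-05; adjusted p = 0.596 with an estimated correlation), by 0.11 within the slide and 0.22 with the block, and none of 32 passed. Interferon-stimulated genes stood higher by 0.20 (adjusted p = 0.0174; adjusted p = 0.932 with an estimated correlation), with Rsad2 (0.90) and the GTPase gene Gbp2 (0.86) the 2 of 40 that rose, or 3 adjusted over the list alone. That shift was 0.01 within the slide, 0.19 with the block (adjusted p = 0.21) and 0.07 without miR-467c precursor replicate 1 (adjusted p = 0.64), and Rsad2 and Gbp2 did not pass with the block (limma adjusted p = 0.060 and 0.18). Unfolded protein response genes (0.17, adjusted p = 0.0151; adjusted p = 0.476 with an estimated correlation) stood higher although their 1 passing gene of 26, the chaperone gene Dnajb9, fell (-0.54), and 2 rose and 1 fell adjusted over the list alone. Heat shock and proteasome genes stood higher by 0.12 (adjusted p = 0.0283; adjusted p = 0.747 with an estimated correlation), with Hspb1 (0.44) the 1 of 24 that rose. These and the unfolded protein response genes were not called with 40 arrays (adjusted p = 0.0987 and 0.0630). Reported miR-23 targets stood lower by -0.06 (adjusted p = 0.0151; adjusted p = 0.424 with an estimated correlation) and at 0.04 with the slide block of the fit of 40 arrays. Their level was 0.09 in the precursor control and 0.0018 with miR-467c (log2, centred on the mean of 39 arrays), so that here too the control stood high. Ppargc1a (-0.96) and the growth factor receptor gene Met (-0.59) were the 2 of 28 that fell, or 5 adjusted over the list alone. Ppargc1a did not pass with the slide block (adjusted p = 0.091), nor Met without control replicate 2 (-0.35, adjusted p = 0.29). TGF-beta response genes were called with 40 arrays alone (0.12, adjusted p = 0.0288; adjusted p = 0.937 with an estimated correlation).

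The miR-466a and miR-466d precursors, from 1 microRNA family, moved Dpy19l4 in opposite directions. Set against each other directly, Dpy19l4 was higher with miR-466a by 1.84 ± 0.18 (log2, SE; limma adjusted p = 3.5e-08 with 40 arrays and 1.6e-09 with 39). It lay at -1.68 ± 0.21 against -3.52 ± 0.25 (SD, n = 4 each), while the control lay at -2.65 ± 0.26. The difference was 1.85 with the slide block and 1.72 to 1.93 when 1 array was left out of the fit of 39. The deubiquitinase gene Usp37 was higher by 1.01 ± 0.22 (adjusted p = 0.0093), and Cd300a (-1.89 ± 0.39, adjusted p = 0.0066), Il4ra (at least 2.61-fold, adjusted p = 0.0053) and Ccdc169 (-1.79 ± 0.38, adjusted p = 0.0093) were lower with miR-466a. Dpy19l4, Usp37, Cd300a and Il4ra passed in all 8 runs with 39 arrays, and Pa2g4 (0.52), Egr3 (at least 1.69-fold lower) and Slc51a (at least 1.22-fold lower) passed with 39 arrays alone. The fit of 40 arrays gave 2 higher and 127 lower features, of which 118 of the lower ones lay in the set of 130 probes, and the fit of 39 gave 7 and 154, with 123 in that set. Without the probe sets Dpy19l4 was the 1 feature that passed with 40 arrays, and Usp37, Cd300a, Il4ra and Ccdc169 kept their log2 changes and lost their calls (adjusted p = 0.121, 0.0896, 0.0776 and 0.121). With 39 arrays 5 features passed, among them Dpy19l4, Cd300a and Il4ra, while Usp37, Ccdc169, Pa2g4, Egr3 and Slc51a did not (adjusted p of 0.0554 to 0.205). Without miR-466a precursor replicate 1 or miR-466d precursor replicate 4 the fit of 40 gave 1, while without miR-466a precursor replicate 1 the fit of 39 gave 102.

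Ribosomal protein genes stood lower with miR-466a than with miR-466d by a median of -0.32 (camera adjusted p = 2.6e-13 with 39 arrays; adjusted p = 0.349 with an estimated correlation), where none of 32 genes passed and 15 fell adjusted over the list alone. The same shift was -0.16 to 0.03 on the 2 shared slides, -0.29 with the slide block, -0.16 without miR-466a precursor replicate 1, and 0.04 under quantile normalisation. Interferon-stimulated genes stood lower by -0.24 (adjusted p = 0.0040; adjusted p = 0.553 with an estimated correlation), at -0.75 to -0.35 on slides and -0.49 with the block, and had an adjusted p of 0.14 without miR-466a precursor replicate 4. Mitosis genes (0.10, adjusted p = 0.00041) and RNA silencing genes (0.09, adjusted p = 0.0040) stood higher, each with an adjusted p = 0.209 with an estimated correlation. Unfolded protein response (0.06), p53 (0.07), TGF-beta (0.08), extracellular matrix (0.07) and apoptosis genes (0.06) stood higher with adjusted p of 0.0125 to 0.0444, each at adjusted p = 0.430 with an estimated correlation. On the 2 shared slides these ran from 0.04 to 0.14, -0.01 to 0.08, -0.0043 to 0.15, -0.03 to 0.16 and 2.7e-05 to 0.06 in the same order, so that p53, TGF-beta and extracellular matrix genes stood lower on 1 of them. The TGF-beta, extracellular matrix and apoptosis lists were not called with 40 arrays (adjusted p = 0.0557 each). No member of these lists passed.

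In the 4 inhibitor comparisons no feature passed in either fit (limma), and no shift was called for the lists of reported targets of the inhibited microRNAs. Small shifts of these lists are not excluded by this. Reported miR-23 targets, which would rise if the microRNA had held them down, changed by a median of 0.07 with the miR-23b inhibitor (27 genes, camera adjusted p = 0.966). Reported miR-30 targets changed by 0.01 with the miR-30a inhibitor (32 genes, adjusted p = 0.885) and -0.02 with the miR-30d inhibitor (adjusted p = 0.827), and reported miR-125 targets by 0.07 with the miR-125a inhibitor (30 genes, adjusted p = 0.519). The features at an unadjusted p below 0.05 numbered 681, 445, 290 and 702 for the miR-23b, miR-30a, miR-30d and miR-125a inhibitors with 40 arrays and 2265, 1199, 838 and 1848 with 39. The smallest adjusted p with 39 arrays were 0.252, 0.635, 0.711 and 0.275. All other settings gave 0 features, apart from 1 without inhibitor control replicate 1 in all 4 comparisons, and in the fit of 39 arrays 1 without miR-30d inhibitor replicate 2 and 1 without miR-125a inhibitor replicate 3.

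The genes with the lowest p-values under the inhibitors did not pass. With the miR-23b inhibitor these were the gene Fgd1 (-0.67 ± 0.17), the Notch target gene Hey1 (1.58 ± 0.39) and the calcium-binding protein gene Pvalb (0.87 ± 0.24) with 40 arrays (log2, SE). With 39 arrays they were Hexdc (-0.48), Ptov1 (-0.38) and Ywhab (-0.42). Hey1 changed by 0.86 without miR-23b inhibitor replicate 1. With the miR-30a inhibitor they were H3c11 (0.57), Lrrc2 (0.71), Rgs7bp (1.12), Dclre1a (-0.34) and Ywhab (-0.33). With the miR-30d inhibitor they were Nbea (0.65), Rbm20 (0.67), Lrrc2 (0.81), Hdhd2 (0.50) and Masp1 (at least 1.20-fold lower). The miR-125a inhibitor gave Pheta2 (-1.27), the matrix gene Fbln2 (1.06), Obox6 (at least 1.17-fold higher), Acat3 (-0.49) and Smarcd2 (-0.58). Interferon-stimulated genes stood higher with the miR-23b inhibitor by a median of 0.37 (camera adjusted p = 6.6e-05 with 39 arrays; adjusted p = 0.998 with an estimated correlation), where none of 40 passed. Slides gave -0.38 to 0.89 and the block 0.37, and the shift was 0.22 without miR-23b inhibitor replicate 4 (adjusted p = 0.081). With the miR-30a inhibitor they stood higher by 0.21 (adjusted p = 0.0044; adjusted p = 0.9896 with an estimated correlation), at -0.30 to 0.81 on slides, and by 0.08 without miR-30a inhibitor replicate 4 (adjusted p = 0.97). Oxidative phosphorylation genes with the miR-30a inhibitor (0.11, adjusted p = 0.0044; adjusted p = 0.9896 with an estimated correlation) and S phase genes with the miR-30d inhibitor (0.06, adjusted p = 0.0374; adjusted p = 0.925 with an estimated correlation) were called with 39 arrays alone. The latter stood lower on both shared slides.

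The inhibitors of miR-30a and miR-30d, which share a seed sequence, were also set against each other. No feature passed in either fit (limma), with 289 at an unadjusted p below 0.05 with 40 arrays and 714 with 39, 13 and 19 passing without miR-30d inhibitor replicate 2, and 309 with array weights. The lowest p-values were those of Ccdc172 (2.54), Defb28 (2.41) and Olfr267 (2.01) with 40 arrays and of Apold1 (at least 1.14-fold higher) with 39, none of which passed. Ribosomal protein genes stood higher with the miR-30a inhibitor by 0.12 (camera adjusted p = 0.0043 with 39 arrays; adjusted p = 0.963 with an estimated correlation), at 0.09 to 0.41 on slides, and at -0.01 under quantile normalisation, and were not called with 40 arrays (adjusted p = 0.0647).

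Single genes differed between the inhibitor control and the precursor control. The monocarboxylate transporter gene Slc16a7 was lower in the inhibitor control by -2.57 ± 0.52 (log2, SE; limma adjusted p = 0.021), the chloride channel gene Cftr by -2.39 ± 0.52 (adjusted p = 0.023) and the muscle protein gene Cmya5 by -2.79 ± 0.62 (adjusted p = 0.025). The RNA receptor gene Tlr7 was higher by 1.27 ± 0.27 (adjusted p = 0.021). Smim6 was at least 1.24-fold and Cst9 at least 1.34-fold higher, and Tmem235 (1.35, adjusted p = 0.017) passed with 39 arrays alone. Spread within the inhibitor control was wide, with Slc16a7 at -2.03 ± 1.83 (SD, n = 4) against 0.54 ± 0.50. Without inhibitor control replicate 4 the changes were -1.72 for Slc16a7, -1.76 for Cmya5 and -1.57 for Cftr (adjusted p = 0.065 with 39 arrays). The fit of 40 arrays gave 34 higher and 120 lower features with 2535 at an unadjusted p below 0.05, and that of 39 gave 535 and 620 with 5085. Without the co-varying probe sets these were 27 and 44 with 40 arrays and 516 and 533 with 39. Quantile normalisation gave 68 and 158, the percentile over probes above background 212 and 393, and the series matrix 233 and 372. In the fit of 40 arrays the count was 5, 8, 76 and 90 without precursor control replicates 1 to 4, and 49, 359 and 10 without inhibitor control replicates 1, 3 and 4. No named gene passed in every run. With 39 arrays it was 545 and 391 without precursor control replicates 1 and 2, and 503, 752, 2358 and 558 without inhibitor control replicates 1 to 4. Slc16a7, Cmya5, Smim6 and Tlr7 passed in all 8 of these runs. The probe of Cmya5 belongs to a co-varying set, and without these sets another probe of the gene changed by -0.43 (adjusted p = 0.814 with 40 arrays and 0.480 with 39). No list was called.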

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

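The tests on other probes of the same genes and the tests on miR-467c precursor replicate 4 were chosen only after the result was seen, and so was the reading of the runs without single control arrays.

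An array was picked out when its gap to the nearest other array of its group took up an unusual share of the range of the 4 arrays, a limit that chance passes in about 1 in 20 groups. For array measures 9 of 40 groups passed it where chance would give 2, and for levels of co-varying probe sets 1 of 40 where chance would give 2. For gene list levels it was 21 of 94 where chance would give 4.7, and for named genes 40 of 340 where chance would give 17. Replicate 2 of the miR-337 precursor accounted for 3 of the array measures, 17 of the list levels and 22 of the named genes.

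Replicate 2 of the miR-337 precursor had 91.8% of its probes well above background against 49.0 to 49.6% on the other 3 arrays, a share of the range of 0.985. Its median correlation with the other arrays was 0.774 against 0.989 to 0.991 (share 0.989), and the low signal of its spike-in curve was 2.41 against 0.27 to 0.34 (share 0.970). Median correlation was also low on miR-23b inhibitor replicate 1, at 0.977 (share 0.874), on precursor control replicate 2, at 0.975 (share 0.904), and on miR-466a precursor replicate 1, at 0.986 (share 0.880). The low signal of the spike-in curve was high on inhibitor control replicate 2, at 0.442 (share 0.898), on miR-466a precursor replicate 1, at 0.400 (share 0.850), and on miR-466d precursor replicate 3, at 0.943 (share 0.936).

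Among gene lists, the junction and keratin genes lay lower on miR-467c precursor replicate 4 (share 0.835), and unfolded protein response genes higher on miR-466a precursor replicate 4 (share 0.854). Ribosomal protein genes lay lower on miR-466a precursor replicate 1 (share 0.856), at -0.56 against -0.03 to 0.06, and TGF-beta response genes higher on miR-467c precursor replicate 3 (share 0.8294). Among named genes, replicate 4 of the miR-467c precursor lay apart for Cdh4 (share 0.879), Col1a1 (share 0.845), Ddit4l (share 0.857), Gprasp2 (share 0.837), Krt18 (share 0.904) and Palm3 (share 0.935). Cdh4 lay at -2.53 there against -3.70 to -3.56. In the precursor control, replicate 2 lay apart for Atp6v0a4 (share 0.915), Plau (share 0.947) and Met (share 0.902), replicate 3 for Ccl5 (share 0.920), Egln3 (share 0.901) and 1 gene not named here (share 0.855), replicate 4 for Eya1 (share 0.853) and replicate 1 for H2bc8 (share 0.893). Under the inhibitors and the miR-466d precursor, Ywhab lay apart on miR-30a inhibitor replicate 4 (share 0.832), Nbea on miR-30d inhibitor replicate 3 (share 0.884), Ccdc172 on miR-30d inhibitor replicate 2 (share 0.888) and Usp37 on miR-466d precursor replicate 4 (share 0.831).

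The direct comparison of the miR-466a and miR-466d precursors found differences between effects measured against the same control. It called 129 features in the fit of 40 arrays, among them Dpy19l4 (1.84), Cd300a (-1.89), Ccdc169 (-1.79) and Il4ra (at least 2.61-fold lower, with a fitted value of -1.74 that is no measured size because its probe was at background on the miR-466a arrays), the genes whose response to both precursors was tested directly by limma.

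A set of 130 probes lay at 2.59 ± 0.58 (SD, n = 4) on the miR-466a precursor arrays and at 3.66 ± 0.15 on the control arrays. It also stood out on miR-466d precursor replicate 4, at 4.52 against 3.72 to 3.79 (share 0.916). Other probes of the same genes changed by a median of -0.041 (SD 0.19, 54 probes) where the set changed by -1.09 (SD 0.19), which argues against a fall of the transcripts that name these probes. With slide as a block the difference of the set was 1.02 times that without, which argues against the slides. Array brightness stays open: over 39 arrays the set level had r = -0.482 with log2 of the 75th percentile (permutation p = 0.00521, 100000 resamples, 1 relation computed). Spearman's rho was -0.0769 (permutation p = 0.641), r was 0.0684 without the 2 arrays farthest from the median brightness, and within slides r ran from -0.911 to 0.548. An effect of the miR-466a precursor on whatever these probes bind was not tested and stays open.

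The precursor control stood apart from the mean of the other 9 groups, with 101 features higher and 141 lower in the fit of 39 arrays (limma). Its total of 242 was close to the 243 of the inhibitor control. The miR-466a, miR-337 and miR-467c precursors had 276, 887 and 940, so that standing apart is not particular to the precursor control. Chance values of its 4 arrays stay open: when the inhibitor control was set against 2 control arrays and the precursors against the other 2, both differences had a mean covariance of 0.0267. In simulations of unchanged arrays 3 of 100 reached it, with a mean of 0.00128 and a highest value of 0.0409. A single deviating array stays open, since 26.0% of the 242 features passed again without replicate 2, but 35.5, 37.2 and 60.7% passed again without replicates 1, 3 and 4, so that the loss is not particular to it. With slide as a block 90.5% passed again, which argues against the slides. An effect of the control RNA on the cells was not tested.

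Replicate 4 of the miR-467c precursor showed 4.56% of the difference that the other 3 arrays of its group had from the mean of the 8 groups besides the miR-466a and miR-467c precursors (1727 features, own arrays 85.3 to 92.1%, arrays of the 8 groups -13.8 to 10.9%). A weaker or failed transfection would also give this and stays open. Replicate 4 showed 73.9% of the miR-466a precursor difference from the same 8 groups (343 features, own arrays 64.6 to 165%, others -46.5 to 52.5%). Outside the co-varying probe sets it showed 62.2% (198 features, own arrays 83.9 to 99.0%, others -26.3 to 34.7%). Own arrays helped to choose these features and replicate 4 did not, so the ranges are not like for like. A wrong label stays open and the labelled group was kept. The highest miR-466a precursor array showed 15.4% of the miR-467c difference, which argues against a swap between these groups. The median correlation of replicate 4 with the other arrays was 0.991, within the 0.975 to 0.992 of the rest, which argues against a poor array. The tests outside the probe sets and for a swap were added after 73.9% had been seen.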

How the results depend on the processing

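The fit of 39 arrays and every alternative within it, array weights and the fit without co-varying probe sets were chosen only after the result was seen, and the other alternatives were planned. Where a setting changed a count or a direction the cause was not tested, except that leaving out miR-337 precursor replicate 2 is by construction the effect of that array.

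Counts of features in the fit of 40 arrays were 954 for the miR-337 precursor, 0 for miR-466a, 3 for miR-466d, 15 for miR-467c, 154 for the controls, 129 for miR-466a against miR-466d and 0 for the 5 other comparisons. Normexp correction gave 28 for miR-466a and 9 for miR-467c. Quantile normalisation gave 120, 26 and 68 for miR-466a, miR-466d and miR-467c. The 75th percentile over probes above background on all arrays gave 194, 99 and 362 for these and 605 for the controls, and the series matrix gave 179, 79 and 264 and also 605 for the controls. Without a filter on dim probes the counts were 484 for miR-337, 5 for miR-466d, 7 for miR-467c and 11 for the controls. The mean of a gene's probes gave 2 for miR-466a and 5 for miR-466d. Slide as a block gave 386 for miR-337 and 5 for miR-466a. A fit of only the 8 arrays compared gave 0 for miR-337, 95 for miR-466a, 209 for miR-466d, 507 for miR-467c, 19 for the controls and 2 for miR-466a against miR-466d. The fit of 39 arrays gave 385, 237, 87, 522 and 1155 for miR-337, miR-466a, miR-466d, miR-467c and the controls. Array weights gave 2512, 1027, 432, 3602 and 1069 for these, 309 for the miR-30a against the miR-30d inhibitor and 302 for miR-466a against miR-466d. Without co-varying probe sets 2, 3 and 5 the controls gave 71 and miR-466a against miR-466d gave 1. Other counts stayed within 1.5 times the value first given.

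With 39 arrays, quantile normalisation gave 173 for miR-466d, and the fit without those probe sets gave 73 for miR-466a and 5 for miR-466a against miR-466d. There slide as a block gave 377, 242, 102, 484, 1380 and 180 for miR-337, miR-466a, miR-466d, miR-467c, the controls and miR-466a against miR-466d. A block for replicate number gave 1022, 0, 2, 14, 161 and 126 for these with 40 arrays and 341, 235, 92, 475, 1170 and 164 with 39. Replicate numbers did not pair arrays across groups, since no comparison had every pair of equal numbers correlated above 0.1.

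Leaving out each array in turn gave 205 to 6279 features for miR-337, 0 to 0 for miR-466a, 1 to 2 for miR-466d, 0 to 124 for miR-467c and 5 to 359 for the controls in the fit of 40 arrays. There it also gave 1 to 128 for miR-466a against miR-466d, 0 to 13 for the miR-30a against the miR-30d inhibitor and 0 to 1 for each inhibitor. With 39 arrays the ranges were 121 to 456, 96 to 212, 31 to 50, 105 to 1151, 391 to 2358, 102 to 230, 0 to 19 and 0 to 1 in the same order.

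The number of gene list shifts called over the 8 treatments was 44 in the fit of 40 arrays. It was 27 with quantile normalisation, 25 over probes above background on all 40 arrays, 0 in camera with an estimated correlation and 1 in fry. The fit of 39 arrays gave 32. There fry called 1, 1, 3 and 5 lists for the miR-337, miR-466a, miR-466d and miR-467c precursors, and 0 for each inhibitor. Among them were the p53 list (fry adjusted p = 0.0023) and the mesenchymal list (fry adjusted p = 7.6e-05) with miR-467c, and the junction list with miR-337 (fry adjusted p = 0.0049). The median of the correlations between treatments that share a control was 0.457 and ran from 0.455 to 0.563 over the alternatives.

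Directions of named genes reversed in few settings. In the miR-337 comparison Echdc1, at -0.15 with 40 arrays, was at 0.29 with normexp correction and 0.19 with the percentile over probes above background, and Lhx9, at -0.16, was at 0.26 and 0.17. Plch2 (-0.76) was at 0.11 with normexp correction, and Thpo with miR-467c (-1.40) at 0.0043. These 4 genes lie near background, so that none of these values is a measured size. Leaving out single arrays gave -1.29 to 0.39 for Echdc1, -1.28 to 0.33 for Lhx9 and -0.027 to 0.56 for Krt8. Without the co-varying probe sets, where other probes stand for the same genes, miR-466a gave 0.28 for Arhgap26, 0.065 for Zcchc9, -0.20 for Idua and -0.20 for Slc17a5.

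Most reversed list shifts belong to the miR-337 comparison with 40 arrays. With normexp correction the inflammatory list was at -0.028 there, and glycolysis genes with miR-466a at -0.021. Quantile normalisation gave -0.018 for the junction list with miR-337, -0.017 for ribosomal genes with miR-466d, -0.013 for them in the miR-30a against the miR-30d inhibitor and 0.044 in miR-466a against miR-466d. With miR-337, the percentile over probes above background gave 0.0048 for S phase and 0.0054 for G2/M genes, and the series matrix gave 0.053 and 0.052 for these, 0.0060 for oxidative phosphorylation and 0.022 for heat shock genes. Probes above background on all 40 arrays gave -2.3e-06 for the club cell list, -0.14 for the junction list and -0.093 for the inflammatory list. Slide as a block gave 0.038 for reported miR-23 targets with miR-467c. The fit of 39 arrays gave 0.052 for S phase, 0.038 for G2/M, 0.035 for ribosomal, 0.0028 for heat shock and 0.0043 for TGF-beta response genes. Array weights gave 0.067 for S phase, 0.051 for G2/M, 0.0012 for p53, 0.019 for oxidative phosphorylation, 0.050 for heat shock, 0.0030 for extracellular matrix and 0.010 for apoptosis genes.

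Leaving out single arrays moved the lists of the miR-337 comparison over wide ranges. Interferon-stimulated genes ran from -0.079 to 0.77, inflammatory genes from -0.081 to 0.12, S phase genes from -0.50 to 0.052 and G2/M genes from -0.48 to 0.038. The ranges were -0.52 to 0.035 for ribosomal genes, -0.48 to 0.0028 for heat shock genes and -0.52 to 0.0043 for TGF-beta response genes.

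Of the genes named from either fit, most of which did not pass with 40 arrays, 160 kept their direction and their side of an adjusted p of 0.05 with slide as a block of that fit, 16 lost a call and 3 gained one. Quantile normalisation left 137 so, with 20 losses and 22 gains, and normexp correction 143, with 26 losses, 6 gains and 4 reversals. Signal over background limits the dim genes, for which only bounds are given. Alternatives for seed sites, fixed beforehand, were not run.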

Other observations

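The correlations between comparisons and the counts of other splits were planned, while the fit of 39 arrays, the genes shared by the precursors, the contrast of each group with the other 9 and the structure within groups were chosen only after the result was seen.

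A few genes moved the same way with all 4 precursors in the fit of 39 arrays (limma), all measured against the same 4 control arrays. The SUMO protease gene Senp2 was higher by 0.40, 0.54, 0.48 and 0.63 (log2; miR-337, miR-466a, miR-466d and miR-467c precursors), and the centrosome gene Ssx2ip by 0.65, 0.60, 0.54 and 0.77. The RNA export gene Fyttd1 was higher by 0.55, 0.49, 0.47 and 0.42, and the chaperone gene Fkbp9 by 0.40, 0.60, 0.45 and 0.40. The cell cycle gene Ccnd2, which encodes cyclin D2, was lower by -0.77, -0.50, -0.49 and -0.41, Crb2 by -0.87, -0.82, -0.88 and -1.04, Lpin2 by -0.62, -0.51, -0.86 and -0.76, and Slpi by -0.77, -0.81, -0.91 and -0.71. These genes differed in the same direction between the inhibitor control and the precursor control, at 0.43, 0.68, 0.56 and 0.32 for the higher ones and -0.35, -0.83, -0.65 and -0.61 for the lower ones. Of these, Slpi did not pass (adjusted p = 0.053). At least 3 precursors shared 24 higher and 11 lower features, and 19 and 7 of these also passed between the controls. Among those of 3 precursors, Ccl2 was lower with miR-466a (-0.97), miR-466d (-1.14) and miR-467c (-0.64), H1f2 was higher with them (0.80, 0.72 and 0.83) and Mgat3 lower (-0.86, -0.55 and -0.43), while Mgat3 did not differ between the controls (0.03, adjusted p = 0.898). Whether miR-337 differs from them for these genes was not tested. Among the miR-467c precursor arrays Ccl2 lay at 2.13 on replicate 4 and at 2.91 to 3.01 on the others, so that its fall there rests partly on replicate 4.

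The changes of the precursor groups correlated across 24009 features, which are not independent replicates, and a shared control alone gives such values. Between miR-466a and miR-467c r was 0.647, with a covariance of 0.0732. Simulated unchanged groups with a shared control had a mean r of 0.528, a highest r of 0.743, a mean covariance of 0.0374 and a highest of 0.0752 (100 simulations). With each group set against its own 2 control arrays r was 0.244, and 39 higher and 15 lower features were shared. A shared control alone adds to such counts, and how many it would give was not simulated. Replicate 4 of the miR-467c precursor, for which a wrong label stays open, showed 73.9% of the miR-466a difference and is part of these values. What r and the shared features would be without it was not computed. The other pairs, in the order miR-337 with miR-466a, miR-466d and miR-467c, then miR-466d with miR-466a and miR-467c, had r of 0.449, 0.363, 0.534, 0.298 and 0.395 and covariances of 0.0527, 0.0376, 0.0673, 0.0277 and 0.0395. With split controls their r was 0.0993, 0.0161, 0.186, -0.0662 and 0.0294. They shared 13, 8, 20, 24 and 24 higher features and 5, 5, 17, 18 and 22 lower ones. Inhibitor pairs had r of 0.428 to 0.624 against a simulated mean of 0.496 with a highest of 0.737, and -0.129 to 0.0135 with split controls.

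Each group was also set against the mean of the other 9 in the fit of 39 arrays (limma). The miR-467c precursor had 542 features higher and 398 lower, the miR-337 precursor 269 and 618, the miR-466a precursor 80 and 196, the inhibitor control 69 and 174, the miR-30d inhibitor 15 and 11 and the miR-466d precursor 2 and 11. The inhibitors of miR-23b, miR-30a and miR-125a had 0 at an adjusted p below 0.05. For the precursor control it was 101 higher and 141 lower.

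The 8 arrays of each comparison were regrouped into all 35 splits of 4 against 4, or with 39 arrays into 35 splits of 3 against 4 where miR-337 is involved, and the calls were counted again. With 39 arrays the real split gave more features than any other for miR-337 (385, highest other 106) and miR-466a (237, highest other 1). The same held for miR-466d (87, highest other 3) and miR-467c (522, highest other 273). It held too for the controls (1155, highest other 412) and miR-466a against miR-466d (161, highest other 1). This argues against chance in how these arrays were grouped. A share of 1 in 35 is the lowest that this test can give. It was run on every comparison in both fits without adjustment, so that chance is not excluded. These counts test how the arrays compared were grouped and not which group deviates, so that chance values of the 4 precursor control arrays stay open. With 40 arrays the real split gave the most for the controls (154, highest other 0) and miR-466a against miR-466d (129, highest other 0). It also gave the most for miR-466d (3, highest other 2) and miR-467c (15, highest other 13), but by so little that chance stays open there. Chance stays open too for miR-337 with 40 arrays, where 3 of 35 splits gave as many as the real 954 and the highest other gave 1491. For miR-466a with 40 arrays the real split gave 0 and the highest other 1. For the inhibitors of miR-23b, miR-30a, miR-30d and miR-125a and for miR-30a against miR-30d the real split gave 0. Every split reaches that count, so this test cannot tell about chance there. The highest other splits gave 0, 0, 329, 549 and 6 with 40 arrays and 0, 5281, 4608, 6706 and 17 with 39. Splits that call 5281, 4608 or 6706 features where the real one calls none point to a structure of the samples that the groups do not follow.

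Whether the largest component within groups is that structure was not tested. Over 39 arrays this component held 15.1% of the variance within groups, of which 6.45% lay between slides. The 100 features that led it had a median level of -5.25 where all features had -0.26, so that they were dim, and 37 of them had a symbol. What set this component was not tested.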
